A study of Caenorhabditis elegans with 2 samples.

How the data were processed

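Chromatin immunoprecipitation against GFP was done in 2 biological replicates of whole L4 larvae that carried a dmd-8 EGFP transgene, per the labels. The worms were synchronised by starvation at the L1 stage after bleaching and chromatin was broken by sonication, per the labels. The 8 peak lists used are the authors' deposited lists on assembly ce11, per the labels. They comprise, for each replicate and for the replicates combined, IDR thresholded lists (for the combined replicates a conservative and an optimal list) and the longer IDR ranked lists from which those were drawn. The irreproducible discovery rate (IDR) measures how well the ranks of peaks repeat between 2 compared lists. The deposited notes name a control file among the sources of the lists. The control's own data were not analysed here. The aligner, the peak caller and their versions are not given in the sources used here.

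Each deposited list gives, per peak, the authors' signal value from the peak caller, which is not scaled between lists. It was used to rank or compare peaks within a list and, for the same peaks, to correlate and plot the 2 replicates' values. It also gives the authors' score, set from the IDR of the peak, and the authors' −log10 q-value of the peak caller, which was not used. The ranked lists carry a deposited −log10 IDR per peak, read as a score. Every peak of the thresholded lists had an IDR of 0.01 or less in the matching ranked list. The thresholded lists left out some ranked peaks under that limit, and per the deposited notes they rest on a further file whose content is not given in the sources used here. Peaks were called by the authors per replicate and on combined replicates, so the replicate lists can be compared directly and the conservative list rests on both. With a single group of 2 replicates, tests compare peaks with shifted or flanking positions, and no p-value measures the spread between worms.

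The genes, transcripts and biotypes came from Ensembl release 115 for the same assembly, the sequence and tRNA isotypes and tRNA pseudogenes from the RefSeq annotation of that assembly. Peak ends in every list lay inside the chromosome lengths of that sequence. Positions are 1-based. The conservative list was the main peak set. A gene was bound when a summit lay from 1000 bp upstream to 200 bp downstream of its annotated 5′ end, over 19973 nuclear protein-coding genes. Each summit had 1 location class, in the order promoter, 5′ UTR, 3′ UTR, coding exon, intron, noncoding RNA gene and intergenic. Circular shifts moved all peaks of a chromosome by a single random offset, in 1000 draws. The test was one-sided for replicate overlap, promoter share and noncoding classes and two-sided for location classes, with Benjamini-Hochberg adjustment over classes. For replicate overlap the minimum overlap was 1 bp.

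The 32 gene lists and 22 motifs were fixed before the data were examined. Each list was tested against all other protein-coding genes with a two-sided Fisher's exact test and with a circular shift of the bound marks along the gene order in 1000 draws, and was called only when both passed 0.05 after adjustment. Single gene names without a match in the annotation were left out, and the heterochronic list kept 15 of its 20 names. Lists with at least 5 bound members entered a permutation test of median signal rank with 100000 resamples. Motifs and 6-mers on either strand were compared between 100 bp at the summit and 100 bp centred 300 bp away on a side drawn with a fixed seed, with an exact McNemar test. The X share was tested with an exact binomial test, and intervals of shares are exact (Clopper-Pearson) 95% intervals. They cover counting of peaks or genes only.

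Named were the 20 peaks of highest signal with the genes whose promoter window holds the summit or else the nearest 5′ end, every DM domain gene, unc-119, and in each called list the 4 bound members of highest signal. The genes that hold the peaks near dmd-8 and the host genes of named summits were named after their values were seen. Alternatives were the optimal list, each replicate's list alone, the peaks of higher signal, other windows and distances, other overlap rules, other backgrounds, sets of peaks chosen after the data were seen and, also added then, all offsets of the gene order in place of 1000 draws. The scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

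The tests were tested on simulated data. Simulated lists held 60 of 19973 genes. With bound genes planted at 5 times the usual rate the list test called 14 of 20 lists, and without a planted change 0 of 20. Members were drawn at random and bound independently, and as many lists were planted as not. The list runs thus do not measure calls for lists of neighbouring genes or with few true lists. With 200 draws the circular shift called 20 of 20 peak sets with a planted 2% share at tRNA genes and 0 of 20 without. Motifs planted in 5% of summit windows were called in 3 of 3 cases, and 0 of 63 motifs not planted were called. Both simulated windows were shuffled from the same flank and so shared a base composition. Real summits had a median GC content of 51% and flanks 36%, so these runs do not measure false calls from that difference. Mitochondrial peaks, present in the replicate 2 list only, were left out of every test.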

Results

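Binding of DMD-8 was measured by chromatin immunoprecipitation and sequencing in whole Caenorhabditis elegans at the L4 larval stage, 48.5 hours old. DMD-8 belongs to the DM domain family, transcription factors related to Doublesex and MAB-3 that act in sexual development and other processes. The worms carried an integrated transgene with dmd-8 fused to EGFP, and an antibody against GFP was used. The single group had 2 biological replicates, and no untreated or control list was analysed here, so the comparisons are between genomic regions and not between conditions. The question, as far as the labels give it, is where in the genome the tagged protein was found. The replicate lists held 629 peaks for replicate 1 and 545 for replicate 2, a ratio of 1.15. The conservative list, made by the authors from both replicates, held 1537 peaks and their optimal list 1556. Read depth per replicate is unknown from peak lists, and the intervals given below cover counting of peaks only.

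The strongest binding in the conservative list lay at genes of small structural RNAs. Of the 20 peaks with the highest signal value, 11 had a snoRNA or snRNA gene within 200 bp of the summit, 3 a tRNA gene and 6 neither. The highest, on chromosome V from 8500445 to 8500684 (ce11), had a signal of 646 and lay in an intron of pxn-1, a peroxidasin gene, beside the snoRNA gene ZK994.7. The next lay on V from 12303521 to 12303745 (signal 582) in an intron of frm-7, with F55C5.17 as the nearest protein-coding 5′ end, and on V from 11314095 to 11314324 (signal 531) in an intron of cutl-18, both within 200 bp of a snoRNA gene. The peak on I from 13463838 to 13464074 (signal 528) had its summit in an intron of ints-8 and inside rpr-1, the gene for the RNA component of RNase P.

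The remaining peaks of that set had signals from 301 to 491. The summit on IV from 1831283 to 1831505 (signal 491) lay in an intron of cmk-1, a calmodulin-dependent kinase gene, and ccm-2 had the nearest 5′ end. Only 3 of the 20 summits fell in a protein-coding promoter window, those of sre-23 (a chemoreceptor gene, signal 431), wrt-3 (314) and Y75B12B.11 (307), and all 3 also lay beside a snoRNA gene. For the others the nearest 5′ ends were those of W03C9.1, Y23H5B.5, twk-5, M02F4.2, pamn-1, nhr-277, wht-2, eif-3.G, C04A11.5, F15G9.5, cdc-25.2 and Y106G6H.9. The summit nearest nhr-277, on IV from 2740141 to 2740303, lay at an annotated tRNA pseudogene. In introns lay 9 of the 20 summits, and 7 were intergenic. Signal values are those of the authors' peak caller and rank peaks within a list only.

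Peaks of the replicates coincided far more often than shifted peaks. Of the replicate 1 peaks, 55.8% (351 of 629, exact 95% interval 51.8% to 59.7%) overlapped a replicate 2 peak by at least 1 bp, against a mean of 0.269% after circular shifts along the chromosomes. Of the 528 nuclear replicate 2 peaks, 65.9% (348, interval 61.7% to 69.9%) overlapped a replicate 1 peak. The one-sided p was 0.001 for each, the smallest that 1000 draws can give, and draws that kept promoter peaks inside promoter windows gave a mean of 0.292% and the same p. Over the 1511 conservative peaks with a value in both ranked lists, Spearman's rho of the signal was 0.49. This is a correlation across peaks, which are not independent replicates. It was 0.63 over peaks at tRNA genes, 0.85 over peaks at snoRNA or snRNA genes and 0.175 over the 1081 other peaks. The conservative peaks were selected for ranks that repeat. Over all 95232 peaks of the pooled ranked list, rho of that list's own 2 signal values was 0.325.

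Many peaks of the conservative list were in neither replicate's own list. These numbered 877 (57.1%), while 311 were in a single replicate's list and 349 in both. The median signal was 80.9 in the first set and 165.9 in the last. Summits within 200 bp of a tRNA gene made up 8.32% of the first set and 51.6% of the last, and summits in coding exons 21.9% and 2.01%.

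**Figure D1:**
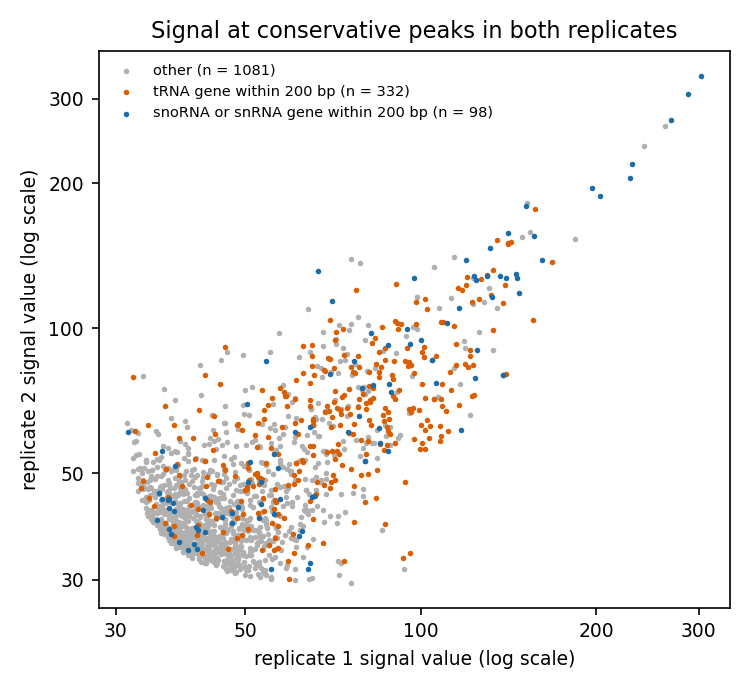
Signal value of each conservative peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), 1 point per peak with a value in both ranked lists. Peaks at tRNA genes (332 points) and at snoRNA or snRNA genes (98) reach higher in both replicates than most of the 1081 other peaks, and rho over all points was 0.49.

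Transfer RNA genes were the most frequent sites among the noncoding classes of small RNA. A tRNA gene lay within 200 bp of 337 of the 1537 summits, 21.9% (exact 95% interval 19.9% to 24.1%), against a mean of 0.282% after circular shifts, a 77.7-fold difference. Small nucleolar RNA genes lay near 79 summits (5.14% against 0.183%) and spliceosomal and other snRNA genes near 21 (1.37% against 0.0599%). The adjusted one-sided p was 0.002 for each of these classes (circular shift, Benjamini-Hochberg over 8 classes), and no draw reached the observed count. The replicate lists gave 39.3% and 42.4% for tRNA genes and 9.38% and 9.66% for snoRNA genes. Of the summits near a gene, 259 lay inside the tRNA gene itself and 10 inside the snoRNA gene (0.651% of summits, against 0.0483% after shifts). By the same permutation of positions, genes of microRNAs lay near 6 summits (adjusted p = 0.0144) and lincRNA genes near 11 (adjusted p = 0.024), while antisense RNA genes, near 5, did not pass (adjusted p = 0.0856). No summit of the conservative list lay near an rRNA gene (0 of 1537, exact 95% upper limit 0.24%, circular shift p = 1). A count of 0 always gives that p in a one-sided test for excess. Of the 141 ranked peaks with an IDR of 0.01 or less that this list leaves out, 3 lay near an rRNA gene. The broad ncRNA class of the annotation lay near 350 summits (22.8% against 3.54%, permutation by circular shift, adjusted p = 0.002). These include summits already counted in the classes above. Without peaks at tRNA, snoRNA or snRNA genes it lay near 106 of 1101 summits (9.63% against 3.31%, one-sided permutation p = 0.001). In the replicates' own lists the microRNA class did not pass the permutation test (adjusted p = 0.0826 and 0.217), and the lincRNA class passed with the replicate 1 list (adjusted p = 0.0368) and not with the replicate 2 list (adjusted p = 0.279).

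Counted by gene, 365 of the 612 nuclear tRNA genes (59.6%, interval 55.6% to 63.6%) had a summit within 200 bp. The share was 43.95% with the replicate 1 list and 40.4% with the replicate 2 list. Of 346 snoRNA genes 78 had a summit (22.5%), and of 129 snRNA genes 21 (16.3%). Annotated tRNA pseudogenes had a summit in 10 of 209 cases (4.78%, interval 2.32% to 8.62%). Among 21 tRNA isotypes the share ran from 40% (8 of 20 tRNA-His genes) to 76.9% (10 of 13 tRNA-Cys genes), leaving aside the single tRNA-Sec gene, which had a summit. No isotype differed from the other tRNA genes after adjustment (Fisher's exact test, lowest adjusted p = 0.496), and 2 had an unadjusted p under 0.05.

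**Figure D2:**
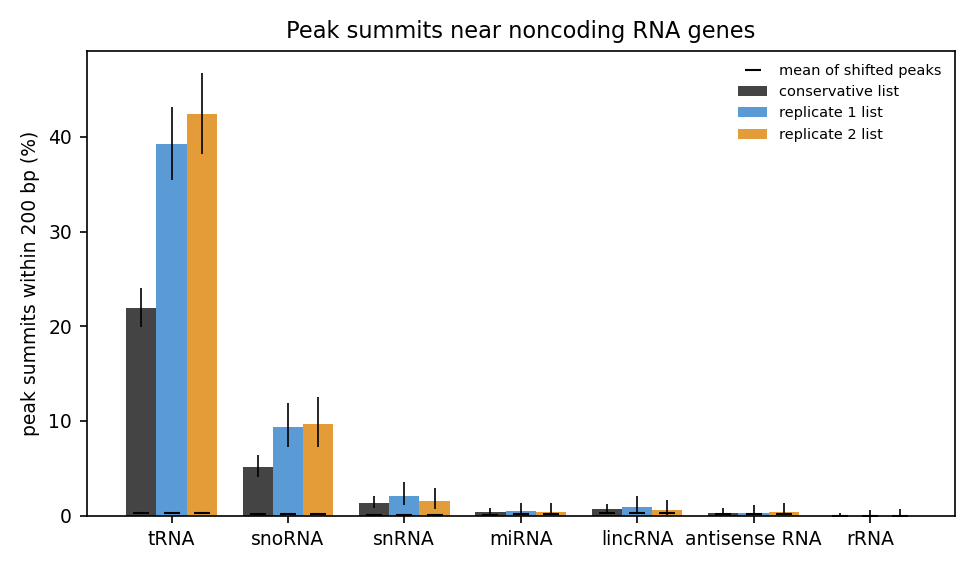
Share of peak summits within 200 bp of a gene of each noncoding class (y axis, percent) in the conservative list and each replicate's list, with exact 95% intervals as error bars and the mean after circular shifts as a black dash. The tRNA share is 21.9%, 39.3% and 42.4% in the 3 lists, against 0.282% after shifts of the conservative list.

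The location of peaks changed with their signal. Among the quintile of conservative peaks with the highest signal, 54.2% (167 of 308, interval 48.5% to 59.9%) lay at tRNA genes, and among the quintile with the lowest 3.91% (12 of 307, interval 2.04% to 6.73%). Coding exons held 1.62% of summits in the highest quintile and 23.5% in the lowest. Promoter windows held 25.3% and 29.0%.

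**Figure D3:**
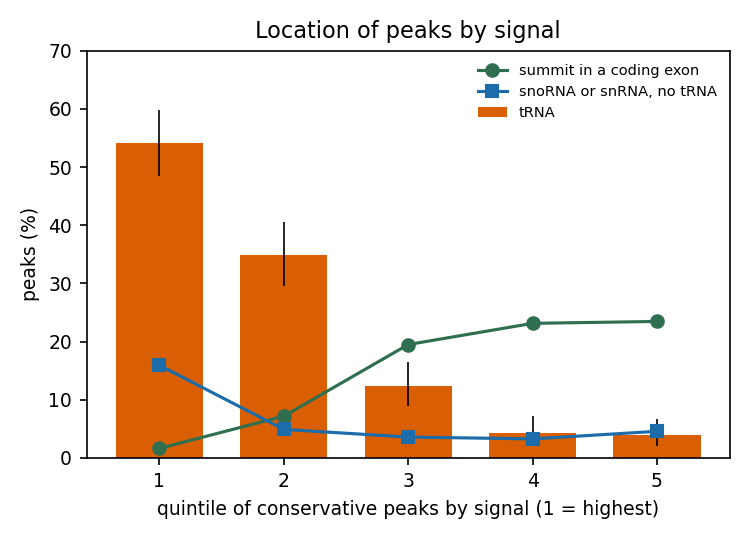
Share of summits (y axis, percent) at tRNA genes (bars, exact 95% intervals), at snoRNA or snRNA genes without a tRNA gene nearby (squares) and in coding exons (circles), by quintile of the conservative peaks ranked by signal (x axis, 1 is the highest). The tRNA share is 54.2% in the first quintile and 3.91% in the last.

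Chromosome X carried a larger share of peaks than of genes. On X lay 295 of the 1537 conservative peaks, 19.2% (exact 95% interval 17.3% to 21.3%), against 13.7% of protein-coding genes (2731 of 19973; two-sided exact binomial p = 2e-09). X also carried 276 of the 612 nuclear tRNA genes (45.1%), and 148 of the 337 tRNA peaks lay there (43.9%). Summits occurred at 58.0% of tRNA genes on X and 61.0% of those on autosomes (Fisher's exact test, p = 0.457). In the conservative list the share of X did not differ from its 17.7% of the nuclear genome length (exact binomial p = 0.124). Without peaks at tRNA, snoRNA or snRNA genes it was 13.1% (exact 95% interval 11.1% to 15.2%). That interval lies under the length share, and the value did not differ from the gene share (exact binomial p = 0.599). The replicate 1 list had 25.8% on X (interval 22.4% to 29.4%) and the replicate 2 list 26.5% (22.8% to 30.5%), above the gene and length shares.

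Protein-coding promoters held more summits than shifted peaks did. In windows from 1000 bp upstream to 200 bp downstream of the 5′ end lay 448 summits, 29.1% against a mean of 21.2% after circular shifts (one-sided permutation p = 0.001, the smallest that the draws can give). Summits of the noncoding RNA gene class made up 8.33% against 0.799%, and those in 5′ UTRs 1.5% against 0.832% (two-sided permutation by circular shift, adjusted p = 0.0035 and 0.014 over 7 classes). The noncoding class counts only summits outside promoter windows and protein-coding genes, so it is smaller than the share inside any noncoding RNA gene. In the replicates' own lists that class made up 13.5% and 12.9%. Lower than after shifts were coding exons (14.96% against 19.5%), introns (26.7% against 30.8%) and intergenic sequence (17.2% against 24.2%), with adjusted p of 0.0035, 0.0056 and 0.0035. The coding exon share was 5.56% and 5.68% in the replicates' own lists, and without peaks at tRNA, snoRNA or snRNA genes it was 20.1% against 19.75% and did not pass (permutation, adjusted p = 0.833). The 3′ UTR share of 2.15% did not differ from the 2.61% after shifts (permutation, adjusted p = 0.282). The intron share turned higher than after shifts in the replicate 1 list (36.7%, permutation, adjusted p = 0.00839) and was higher without passing in the replicate 2 list (33.5%, adjusted p = 0.214). The 5′ UTR share did not pass in the optimal list (1.35%, permutation, adjusted p = 0.0676) or the replicate 2 list (0.947%, adjusted p = 0.899), and in the replicate 1 list it was lower than after shifts (0.636%, adjusted p = 0.813).

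Promoters of 509 of the 19973 protein-coding genes (2.55%) held a summit, and 99 of these genes also had a summit in both replicates' own lists. Genes for cytosolic ribosomal proteins were bound most often among the larger groups, 17 of 83 (20.5%, exact 95% interval 12.4% to 30.8%) against 2.47% of other genes. Examples were rpl-3 (summit 271 bp from the 5′ end, signal 253), rpl-15 (359 bp, 190.6), rpl-35 (454 bp, 171) and rps-19 (286 bp, 157), each with a peak in both replicates' own lists. Heat shock and chaperone genes were bound in 7 of 61 cases (11.5% against 2.52%), among them the J-domain genes dnj-13 (signal 148), dnj-28 (142) and dnj-19 (103) and the mitochondrial chaperonin gene hsp-60 (120.1). In each replicate's own list 4.92% were bound, and the call was lost with 500 bp or 2000 bp upstream and with the nearest gene only (permutation along the gene order, adjusted p = 0.107, 0.121 and 0.128). Heterochronic genes, which time larval development, were bound in 4 of 15 cases (26.7% against 2.53%), namely nhl-2 (signal 96.1), puf-9 (87.5), myrf-1 (87.2) and lep-2 (75.7), of which only nhl-2 had a peak in a replicate's own list, that of replicate 1. Of 1269 chemosensory receptor genes 6 were bound (0.473% against 2.69%), with sre-23 (signal 431), srh-269 (183), srbc-38 (166) and srz-97 (103.95) highest, and of 395 F-box and MATH-BTB genes 2, fbxa-83 (113) and fbxa-106 (76.4). The peak lay at a tRNA, snoRNA or snRNA gene for 3 of these 6 (sre-23, srh-269 and srz-97), for fbxa-83 and for 1 of the 17 ribosomal protein genes.

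These 5 of the 32 lists passed both Fisher's exact test and a circular shift along the gene order after Benjamini-Hochberg adjustment. The adjusted p was 8.6e-10 and 0.0213 for ribosomal proteins, 0.00569 and 0.0384 for heat shock and chaperone genes, and 0.00386 and 0.0213 for heterochronic genes. It was 1.7e-07 and 0.0213 for chemosensory receptors, and 0.0208 and 0.0384 for F-box and MATH-BTB genes. Core histones (8 of 72), translation factors (5 of 42), mitochondrial respiratory chain (5 of 44) and vacuolar ATPase genes (3 of 20) passed Fisher's test only, with shift-adjusted p of 0.0879, 0.0731, 0.0639 and 0.107. The other 23 lists passed neither, and in 5 lists no gene was bound, those of DM domain genes (0 of 10, exact 95% upper limit 30.8%), the intestine (0 of 51, 6.98%), neurotransmitter identity (0 of 38, 9.25%), cilia (0 of 50, 7.11%) and vulva and gonad development (0 of 39, 9.03%). With the authors' optimal list, core histones passed too (9 of 72, 12.5%, Fisher's exact test, adjusted p = 0.00084, shift-adjusted p = 0.032), while heterochronic genes (20% bound) and F-box and MATH-BTB genes (0.506%) no longer passed, each with a shift-adjusted p of 0.0879. With the replicate 1 or replicate 2 list alone no list could pass by itself in 1000 draws, since the lowest adjusted p of a lone list is then 0.0639, and ribosomal protein genes had that value in each. They were bound in 12.05% and 10.8% of cases against 0.895% and 0.779% of other genes (Fisher's exact test, adjusted p = 1.8e-07 and 8.5e-07), and with all offsets of the gene order they were the only list to pass (permutation, adjusted p = 0.00641 in each). Calls near the threshold depended on which offsets were drawn, and all 19973 offsets of the gene order in place of 1000 random ones gave 8 lists, the 5 above and those of core histones, translation factors and the respiratory chain.

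**Figure D4:**
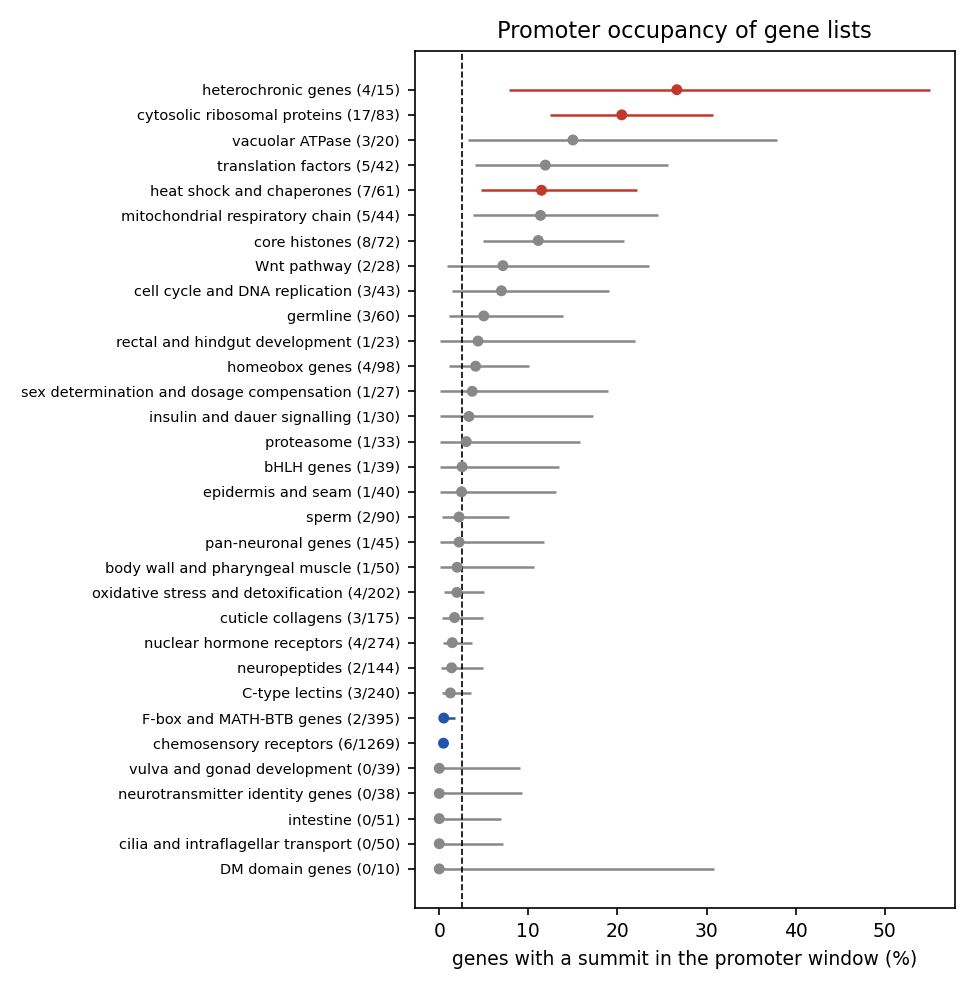
Share of genes with a summit in the promoter window (x axis, percent) for each of the 32 gene lists, as points with exact 95% intervals, and bound and total genes in parentheses. Red lists were higher and blue lists lower by both tests, grey lists were not called, and the dashed line is the 2.55% of all protein-coding genes.

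Signal at bound promoters did not separate any list from the other bound genes. Bound ribosomal protein genes had a median signal rank of 145 among 509 bound genes, against 256.5 for the others (permutation test with 100000 resamples, two-sided p = 0.0571, adjusted p = 0.241). Of the 6 lists with at least 5 bound members 0 passed after adjustment, and 0 had an unadjusted p under 0.05.

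The core DM domain site ACAWTGT was not more frequent at summits. It occurred in 14 of 1537 summit windows of 100 bp (0.911%) and in 27 flank windows (1.76%; exact McNemar test, adjusted p = 0.0936). More frequent at summits by the exact McNemar test were the KLF/SP site CCGCCC (6.96% against 1.63%, adjusted p = 4.5e-13), the GAGA repeat (12.2% against 6.64%, adjusted p = 4.8e-07), the E2F site (6.96% against 3.06%, adjusted p = 1.3e-06) and CAGCTG (3.71% against 1.82%, adjusted p = 0.00386). Less frequent by the same exact test were 8 motifs, among them the TATA box (3.51% against 11.0%, adjusted p = 5.9e-15), the homeodomain site (1.17% against 5.73%, adjusted p = 9.2e-12) and the GATA site (12.6% against 19.8%, adjusted p = 2.9e-07). The POU site, also among the 8, did not pass with the optimal list (exact McNemar test, adjusted p = 0.185) or in 6 other alternatives, the forkhead site not with the replicate 2 list (adjusted p = 0.130) and the HOX/PBX site not against promoters of unbound genes (Fisher's exact test, adjusted p = 0.0975). The remaining 10 of the 22 motifs did not pass. The median GC content was 51% at summits, 36% in flanks and 35.4% in the nuclear genome. The motif and 6-mer tests against flanks did not correct for this difference, so a call may reflect base composition and not a site preference. The DM site is mostly A and T, so its frequency against flanks, in either window size, cannot show whether the site is preferred. CAGCTG did not pass in either replicate's own list (exact McNemar test, adjusted p = 0.484 and 0.609). Among the 448 summits in promoters, set against promoters of unbound genes, neither CAGCTG (Fisher's exact test, adjusted p = 0.0866) nor the E2F site (6.03% against 3.57%, adjusted p = 0.209) passed. In a 200 bp window the DM site was lower at summits (2.15% of windows, exact McNemar test, adjusted p = 0.0302), while among the 448 summits in promoters it occurred in 1.56% of windows, against 1.34% in promoters of unbound genes (Fisher's exact test, adjusted p = 1).

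Of 2080 6-mers, 721 were more and 409 less frequent at summits than in flanks (exact McNemar test, adjusted). The largest excess by that exact test was that of ACCACT (15.3% against 3.12%, adjusted p = 3e-30), CGAACC (14.1% against 2.86%, adjusted p = 2.8e-27) and GTTCGA (15.8% against 5.01%, adjusted p = 1.5e-21), followed by GAACCC, AGAGCG, CGGCCA, CTGAGC, GGCCGA, CACCAC and AACCAC. CGAACC and GTTCGA, parts of the conserved T arm sequence of tRNA, did not differ from flanks in peaks away from tRNA, snoRNA and snRNA genes (3.81% against 3.09%, exact McNemar test, adjusted p = 0.558, and 5.45% against 5.09%, adjusted p = 0.857). The other 8 still passed there, each with a smaller gap between summits and flanks than over all peaks. The smallest gaps were those of GAACCC (4.45% against 2.54%, exact McNemar test, adjusted p = 0.0374) and AACCAC (6.09% against 3.72%, adjusted p = 0.0373). Whether these 8 are also parts of tRNA sequence was not tested.

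Within 20 kb of dmd-8 (V, 334601 to 336450) lay 5 conservative peaks, all on the side of its 3′ end. They lay in introns of nhr-15, a nuclear hormone receptor gene (V, 316977 to 317256, signal 152, and V, 318461 to 318740, signal 56.2), and in coding exons of abt-4, an ABC transporter gene (V, 325071 to 325350, signal 104.4, V, 327657 to 327936, signal 108.3, and V, 328461 to 328740, signal 76.4). The highest ranked 236 of 1537. The replicate 1 list had 1 peak there and the replicate 2 list 3, and within 20 kb of unc-119, whose rescuing copy is on the transgene, no list had a peak. No promoter of the 10 annotated DM domain genes held a summit. The summit nearest the 5′ end of dmd-5 lay inside that gene, 1.26 kb downstream of that end (signal 108.4). Upstream of the 5′ end lay the nearest summits of dmd-10 (3.34 kb, signal 189), dmd-6 (6.63 kb, 81.4) and dmd-7 (19.3 kb, 124). Past the 3′ end lay those of dmd-8 (7.85 kb from the 5′ end, signal 76.4) and dmd-3 (12.1 kb, 267). For the others the nearest summits lay 38.2 kb from mab-3, 39.7 kb from mab-23, 50.95 kb from dmd-4 and 59.0 kb from dmd-9.

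**Figure D5:**
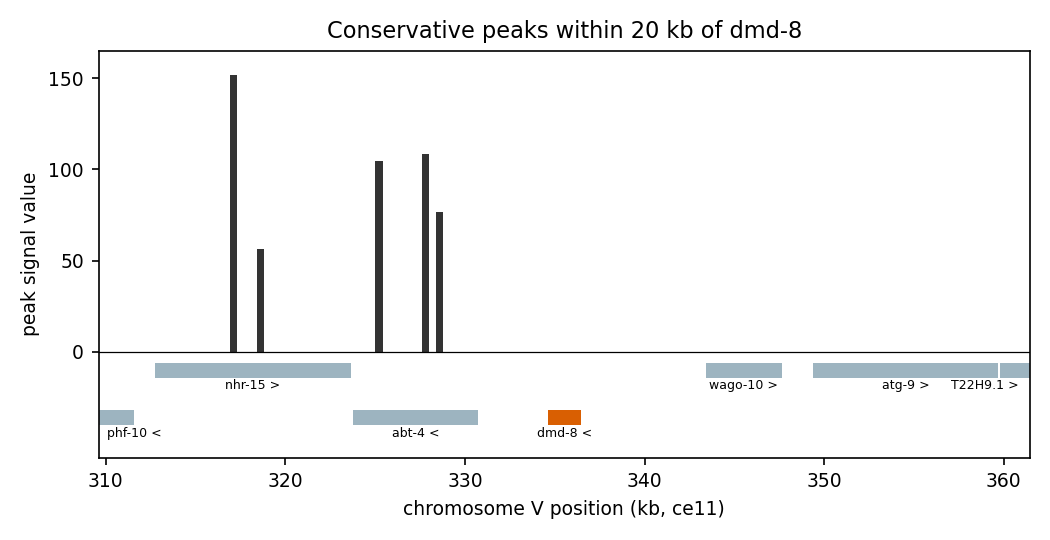
Conservative peaks within 20 kb of dmd-8 on chromosome V (x axis, position in kb, ce11), with the signal value of each peak as bar height (y axis). Protein-coding genes are drawn to scale under the axis with > or < for strand and dmd-8 in orange, and the 5 peaks, with signals from 56.2 to 152, lie in nhr-15 and abt-4.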

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

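The values in this part were looked up after the lists had been seen, and no explanation for them was tested. The replicate 2 list held 17 peaks on the mitochondrial genome and the replicate 1 list 0, both in the thresholded and in the ranked lists, so this is a signal in replicate 2 outside the nuclear peaks used elsewhere. Their signal ran from 89.2 to 2484 with a median of 611, against a highest nuclear signal of 334 in that list, and they covered 27.4% of the 13794 bp of that genome.

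The pooled ranked list held 141 peaks with an IDR of 0.01 or less that the conservative list leaves out, so these are strong peaks outside the set used for locations, genes and motifs. Their median signal was 163, against 90.6 in the conservative list, and 13 of them exceeded its highest value of 646. The highest, on X from 15810945 to 15811213 (ce11), had a signal of 4492. Of the 141, 118 (83.7%) lay more than 200 bp from any annotated gene with piRNA genes set aside, against 18.1% of conservative peaks. Genes of tRNA lay near 0 of them and rRNA genes near 3.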

How the results depend on the processing

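The alternatives chosen only after results were seen were the sets without peaks at tRNA, snoRNA or snRNA genes and with peaks of a replicate's own list, IDR 0.001, the numbers of peaks in single replicates' lists, the pooled list's own replicate values and all offsets of the gene order, for the main and for every other peak set and gene assignment. The promoter share stayed above shifted peaks in all 8 alternatives (18.9% to 44.5%), the tRNA share in all 7 (16.9% to 42.4%) and the replicate overlap in all 3. Where no reason is given below, the cause was not tested.

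The number of peaks was 443 at IDR 0.001 and 545 to 629 in single replicates' lists. Spearman's rho of 0.49 became 0.60 in the 768 peaks of highest signal and 0.175 without small RNA genes, and Pearson's r of log2 signal was 0.73. The X share of 19.2% did not differ from the genome length share (exact binomial p = 0.124). Without small RNA genes the X share was 13.1% and did not differ from the gene share (exact binomial p = 0.599). The X share was 25.8% and 26.5% in the replicates' own lists and 24.9% among peaks of highest signal, with intervals above the gene and length shares. Near dmd-8 lay 1 to 3 peaks in single replicates' lists, 3 among peaks of highest signal and 2 among peaks of a replicate's own list, all smaller sets.

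In place of 5 gene lists, 0 passed in 1000 draws with a single replicate's list, among peaks of highest signal and among peaks of a replicate's own list. The permutation test could not have called a lone list there, as its lowest adjusted p is 0.0639. With all offsets, which removes that limit and the chance of the draw, 1 passed with either replicate's list (0 to 1 over both versions) and 1 among peaks of a replicate's own list, the ribosomal proteins each time, and 3 among peaks of highest signal, which were ribosomal proteins, heat shock genes and chemosensory receptors. The count was 2 with 500 bp upstream (ribosomal proteins and chemosensory receptors, also with all offsets), 3 with 2000 bp (those and the respiratory chain), 3 by nearest gene (those of 500 bp and heterochronic genes) and 8 with all offsets of the main set. Heat shock genes (4.92% bound in each replicate's list) lost their call with each of these 3 gene assignments, and F-box and MATH-BTB genes kept theirs only with all offsets of the main set. Heterochronic genes had 0% to 6.67% bound in single replicates' lists. The DM site occurred in 2.15% of 200 bp windows (lower than flanks, exact McNemar test, adjusted p = 0.0302) and in 1.56% of the 448 summit windows in promoters against 1.34% of unbound promoters (Fisher's exact test, adjusted p = 1). Of 7-mers, a larger family, 1803 differed.

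Intron shares turned higher than after shifts at 33.5% to 36.7% in single replicates' lists, 31.6% among peaks of highest signal and 34.4% among peaks of a replicate's own list, and of these only the replicate 1 value passed (permutation, adjusted p = 0.00839, the others 0.0769 to 0.797). The 5′ UTR share turned lower at 0.636% with the replicate 1 list (0.947% with replicate 2) and at 0.651% among peaks of highest signal. Without small RNA genes the 3′ UTR share (2.72%) and the coding exon share (20.1%) turned higher, neither past the threshold. The intron share of that set stayed lower than after shifts (20.1% against 31.0%, permutation, adjusted p = 0.0035). The 3′ UTR share, lower than after shifts, passed with the replicate 1 list (1.11%, permutation, adjusted p = 0.014), among peaks of highest signal (0.781%, adjusted p = 0.0028) and among peaks of a replicate's own list (1.06%, adjusted p = 0.00839). No paired analysis was possible because there is a single group. Read depth is unknown, so it is open which of these changes it limits.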

Other observations

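The tests of highly transcribed loci, of the X positions of tRNA genes and of transgene copies were chosen only after the results were seen, and so was the choice of peaks named next. Away from tRNA, snoRNA and snRNA genes the peaks were weaker, with a median signal of 84.8 over 1101 peaks, against 136 at tRNA genes and 134 at snoRNA or snRNA genes. Strong ones among them lay in an intron of unc-104, a kinesin gene (II, 7001499 to 7001778, ce11, signal 257), at an annotated tRNA pseudogene, in the promoter window of dhs-8 (II, 14496900 to 14497179, signal 254) and in an intron of mdt-26 (II, 5661788 to 5661937, signal 254). The 6-mer of largest excess in this set was CGTCTC, in 10.4% of summit windows and 2.54% of flanks (exact McNemar test, adjusted p = 1.5e-13).

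Peaks at tRNA genes were set against 4 explanations. For reads shared between near-identical copies, 99 tRNA genes were taken whose exact sequence occurs once in the genome, with no other within 1 kb. Of these 39.4% had a summit (exact 95% interval 29.7% to 49.7%, against 63.5% of the others), which argues against reads shared between identical copies as the whole cause. Copies that differ by a few bases were not set apart, so reads shared between those stay open. Of 15361 windows matched on GC, 0.547% lay near a tRNA gene, against 21.9% of summits and 0.282% of shifted summits. This argues against GC content as the whole cause and leaves a contribution open. For tRNA-like sequence regardless of function, 4.78% of tRNA pseudogenes had a summit, against 59.6% of tRNA genes. How close the pseudogene sequences are to those of tRNA genes was not measured, so these shares cannot decide on that explanation. For a preference of the immunoprecipitation for highly transcribed loci, 20.5% of ribosomal protein genes were bound, against 2.47% of other genes. That share was known before this test was chosen, and transcription was not measured. The share cannot tell such a preference from binding of the tagged protein at these genes, so this explanation stays open. No control immunoprecipitation was analysed here and no biological explanation was tested.

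The higher share of peaks on chromosome X may come from the positions of tRNA genes. Without the peaks near a tRNA gene the share on X was 12.25% (147 of 1200, exact 95% interval 10.4% to 14.2%), against 13.7% of protein-coding genes. X makes up 17.7% of the nuclear genome length, which lies above that interval. No biological explanation was tested.

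The 5 peaks near dmd-8 may come from extra copies of the locus in the transgene. Circular shifts gave a mean of 0.556 peaks there and at most 7 (one-sided permutation p = 0.00899). The median signal of all ranked peaks within 20 kb lay at percentile 99.12 of 10000 windows of that length in replicate 1 and 97.77 in replicate 2. A peak at the native locus stays open, as does the absence of peaks near unc-119, whose rescuing copy is also on the transgene.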
